A study of Rattus norvegicus with 12 samples.

How the data were processed

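Gene expression was measured with arrays in the soleus, a slow postural muscle of the lower leg, of female Wistar rats aged 3 months. Per the labels, a plasmid with the cytomegalovirus (CMV) promoter was brought into the muscle by electric pulses, either empty or carrying the gene for focal adhesion kinase (FAK), a tyrosine kinase of the contacts between cells and their matrix. Muscles were taken 7 days later from rats kept as cage controls. Per the labels, 3 microgram of total RNA was reverse transcribed with gene-specific primers, and the label protocol names 32P-labelled dATP. The series describes a paired comparison of the legs of 1 animal, so each rat gave an empty and a FAK muscle. Titles of 5 pairs share an animal number. The sixth pair is the remaining empty and FAK samples, whose titles carry no number and are equal apart from the construct. The title numbers are taken here as rats, and the rats serve as the replicates.

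The deposited table holds 1 intensity for each of 1185 array elements on each of 12 arrays. The authors' image reading, background treatment and scaling are not given in the sources used here. The deposited intensities are linear and positive, with 0 missing values and 0 values at or below 0. They behave as values that were not scaled between arrays, since array medians differed by up to 15.2-fold. Every array's lowest intensity was more than 51% of its median, so the range below the median was narrow. If that reflects background, fold changes of dim elements are understated, but no background values were used here. Of the element codes, 702 start with R and a digit and 483 with RG. None matched the reference gene table (0 of 1185; assembly GRCr8), so elements are reported by code. The FAK element and 19 gene lists fixed beforehand (contractile, metabolic, adhesion, matrix, stress and other-cell-type genes) were not analysed here, and the transfer of FAK was not checked.

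Choices were made before the data were examined, except where stated. Intensities were quantile normalized between arrays on the log2 scale, with no floor and no filter because no values were marked as undetected. Each element was fitted with lmFit and eBayes of limma 3.58.1 (R 4.3.3), with the animal as a fixed block. P-values were adjusted by Benjamini-Hochberg over all 1185 elements, with a threshold of 0.05. Changes are FAK minus empty on the log2 intensity scale. Single measures were tested over the 6 pairs with an exact two-sided sign-flip permutation test, whose smallest possible p is 0.03125. The rule for named elements took those with an adjusted p under 0.05 and, with too few, those of smallest unadjusted p that moved one way in at least 5 of 6 pairs. It was reduced from 12 elements in each direction to 2, since the codes carry no gene name.

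The pairing was checked on deviations from the group means. The same-numbered arrays, and the sixth pair, correlated between 0.37 and 0.80, all above 0.1. Arrays of different pairs within the same brightness set correlated between 0.40 and 0.68, so the check also reflects these sets. In 9 of 12 arrays the closest array of the other construct was that of the same rat. Between sets these correlations reached at most 0.03, so the closest array always lay in the own set. Each set offers only 2 arrays of the other construct, so many such matches would arise by chance and the support for the pairing is weak. No arrays held identical columns.

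The paired fit was tested on simulated data: 10 simulations, with the deposited arrays' means and residual spread and 100 elements changed by each fold. It recovered 90.9% of elements changed 1.5-fold and 97.6% of those changed 2-fold, with 4.31% of all calls false, and made 0 calls when nothing was changed. These shares hold for folds on the scale of the deposited intensities, with no background removed. Many elements were changed at once, which eases the adjusted threshold, and the noise was drawn independently for each element. The shares therefore do not tell how often a change would be called if few elements changed. The median standard error was 0.08 on that scale and 0.19 after normexp with quantile normalization, which was not simulated. The alternatives set beforehand were the values as deposited, median scaling, leaving out the dimmest 25% of elements, an offset of the 5th percentile (7340 intensity units) before log2, no animal block, the animal as a random block, the 5 numbered pairs only, a variance trend with robust fitting, and leaving out each pair. Normexp background correction (offset 50) before quantile normalization or median scaling, a block for brightness sets, and paired fits within each set were added after seeing the data. The number of arrays limits the precision.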

Results

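Transcript levels were compared between soleus muscles given a FAK construct and the opposite muscles of the same rats given the empty construct. There were 6 FAK and 6 empty muscles, 1 pair from each of 6 rats, and each array reported 1185 elements. The rats are named here by the numbers in the titles (405, 408, 409, 410 and 411), and the pair without a number is called the unnumbered pair.

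Overall brightness split the arrays into 3 sets of 4, each with 2 FAK and 2 empty muscles. Median intensity was between 2213 and 3263 for the unnumbered pair and rat 405. It was between 14790 and 18342 for rats 408 and 409, and between 31103 and 33582 for rats 410 and 411. Within pairs, the FAK array was the brighter one in 3 of 6 rats. The mean difference in the array median was 0.05 ± 0.14 on the log2 scale (SD, n = 6 pairs; exact sign-flip permutation test, two-sided, p = 0.469).

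**Figure D1:**
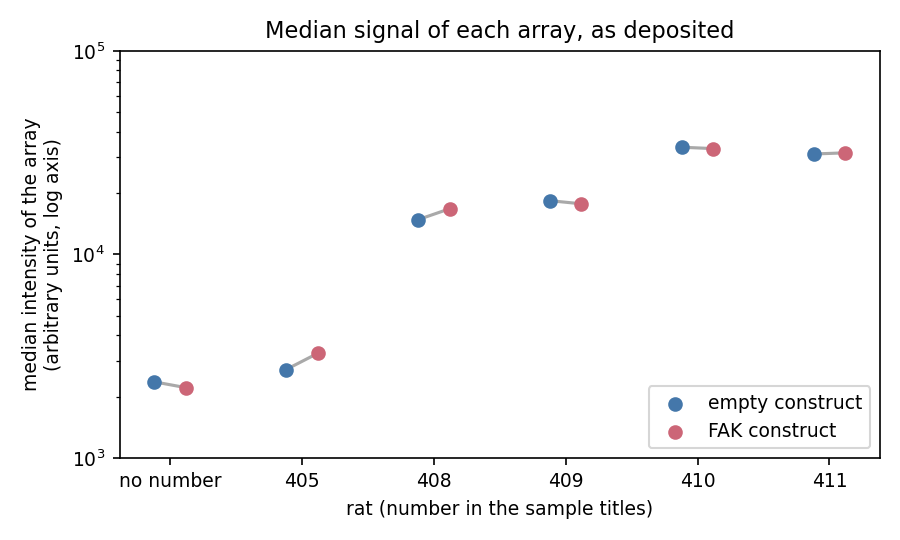
Median deposited intensity of each array (arbitrary units, log axis) for each rat, with the empty construct in blue, the FAK construct in red and a grey line joining the muscles of one rat. The arrays form 3 brightness levels that each hold both constructs, and FAK arrays lie above their partner in 3 of 6 rats.

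The 20 brightest elements of an array carried 37.1% ± 5.2 of the total intensity in empty muscles and 37.5% ± 6.0 in FAK muscles (SD, n = 6 each). The paired difference was 0.35 ± 3.44 percentage points (SD, n = 6 pairs), and it was positive in 3 of 6 rats (exact sign-flip permutation test, two-sided, p = 0.813). The brightest element reached between 71.1 and 456 times the array's median.

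After quantile normalization, the rat and its brightness set accounted for most of the variation between arrays. Pairs held 80.0% of the total variance, against 45.5% for groupings of that size by chance, and brightness sets held 65.6%, against 31.99% for random groupings of the rats into sets of that size. Both muscles of a rat lie in the same set, so the share of the pairs includes that of the sets. What the rat adds beyond its set was not tested. The construct held 4.69%, against a mean of 3.34% when constructs are exchanged at random within rats; this difference was not tested. The correlation of normalized log2 intensities was between 0.932 and 0.982 for the 2 muscles of one rat, between 0.932 and 0.985 for arrays of different rats in one brightness set, and between 0.781 and 0.956 for arrays of different sets.

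The main comparison asked which elements differ between muscles given the FAK construct and those given the empty one, in rats kept as cage controls. Overexpression of FAK is stated in the labels and was not checked here. No element passed the adjusted threshold: the paired limma fit called 0 of 1185 elements higher and 0 lower in FAK muscles, and the smallest adjusted p was 0.600. At an unadjusted p under 0.05, 91 elements differed, 50 higher and 41 lower, where 59.3 would be reached with evenly spread p-values. Without rat 408 this count was 58. With the values as deposited the split was 55 higher and 12 lower, and with median scaling 37 higher and 39 lower. The median change over all elements was 0.00, which quantile normalization largely fixes, and it was 0.04 with the values as deposited.

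**Figure D2:**
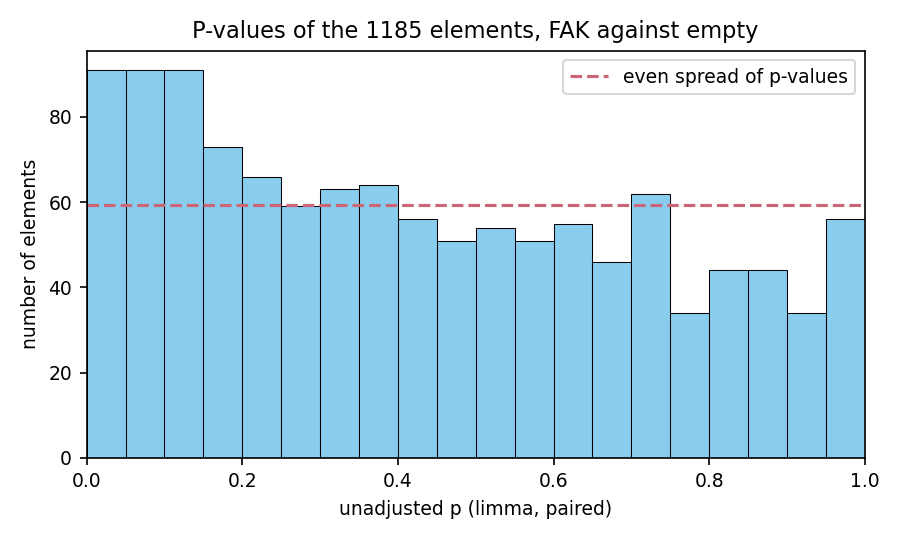
Number of the 1185 elements in each interval of the unadjusted p from the paired limma fit of FAK against empty muscles, with a dashed line for an even spread. The interval of lowest p holds 91 elements against an even spread of 59.3.

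The direction of change was the same in all 6 rats for 61 elements, 40 of them higher and 21 lower in FAK muscles. That is 5.15% of elements, where independent signs would give 3.12%. This count was made only after quantile normalization. The balance of higher and lower elements at an unadjusted p under 0.05 depended on the scaling, so that of the 61 may too. Elements in the brightest 25% made up 38 of the 91 with an unadjusted p under 0.05, and those in the dimmest 25% made up 12. The median standard error of a change was 0.10 in the brightest 25% and 0.06 in the dimmest 25%, on the log2 scale. If a background remains in the intensities, both the changes and the standard errors of dim elements are understated.

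The size of change that these arrays leave open depended on whether a background was removed. Without such a step, the unadjusted 95% interval lay inside a 2-fold change either way for 1168 of 1185 elements (98.6%), and inside 1.5-fold for 1107. The median standard error was 0.08 and the median interval reached 0.17 to either side of the estimate. The largest fitted changes were 0.94 upward and -1.10 downward. After normexp background correction, which assumes an added background, with quantile normalization 951 elements (80.3%) had an interval inside 2-fold and 505 inside 1.5-fold. The median interval then reached 0.45 to either side. With normexp and median scaling, 948 elements had an interval inside 2-fold and 470 inside 1.5-fold.

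The elements that the rule named were those with the smallest unadjusted p and a direction shared by at least 5 rats; none passed the adjusted threshold (limma, adjusted p = 0.600 for each). Element RG103 was higher in FAK than in empty muscles in 6 of 6 rats, by 0.27 ± 0.14 (SD, n = 6 pairs) on the log2 scale, or 1.20-fold. Its normalized log2 intensity was 13.30 ± 0.14 in FAK and 13.04 ± 0.08 in empty muscles (SD, n = 6 each). Element R610 was higher in 6 of 6 rats, by 0.26 ± 0.14 or 1.20-fold, at 13.90 ± 0.21 against 13.63 ± 0.22. Element RG406 was lower in 6 of 6 rats, with a change of -0.24 ± 0.14, at 13.90 ± 0.14 against 14.13 ± 0.08. With normexp and quantile normalization the changes were 0.93 for RG103, 0.51 for R610 and -0.39 for RG406. With the offset added before log2 they were smaller, at 0.15, 0.17 and -0.16.

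Element R371, the third brightest of the array, had the smallest unadjusted p. Its change was -0.60 ± 0.32 (SD, n = 6 pairs), from 20.65 ± 0.42 in empty to 20.05 ± 0.48 in FAK muscles, and it was lower in FAK in 6 of 6 rats. With median scaling the change was -0.26 ± 0.35, lower in 4 of 6 rats (exact sign-flip permutation test, two-sided, p = 0.156). For all 4 elements under quantile normalization the exact sign-flip p was 0.03125, the smallest that 6 pairs can give, before any correction for the 1185 elements. Any element that moves one way in all 6 rats gets this p. The 4 were picked for a small p and a shared direction, so it adds no support to that choice.

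Within brightness sets, the mean changes of RG103 were 0.17, 0.34 and 0.29 from the dimmest to the brightest set, and those of R610 were 0.30, 0.10 and 0.39. They were -0.41, -0.18 and -0.12 for RG406 and -0.90, -0.31 and -0.61 for R371. Each set holds 2 rats, which leaves 1 residual degree of freedom. Paired limma fits within the sets called 0 of 1185 elements in each, with smallest adjusted p-values of 0.834, 0.893 and 0.986 from the dimmest to the brightest set. At an unadjusted p under 0.05 there were 54, 37 and 31 elements, all below the 59.3 that evenly spread p-values would give.

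**Figure D3:**
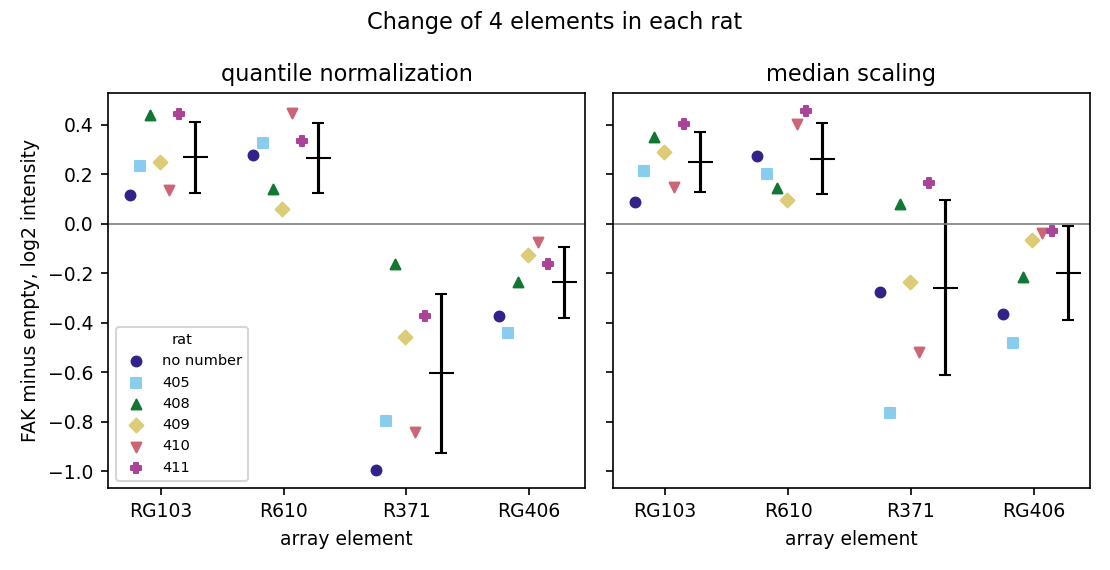
Change from empty to FAK muscle (log2 intensity) of elements RG103, R610, R371 and RG406 in each rat, with 1 marker per rat and the mean ± SD over 6 rats in black, after quantile normalization (left) and median scaling (right). RG103 and R610 lie above 0 and RG406 below 0 in all 6 rats in both panels, while R371 lies below 0 in 6 rats on the left and 4 on the right.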

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

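The count of 0 elements past the adjusted threshold was the same under all 17 alternatives run, with smallest adjusted p-values between 0.227 and 0.999 (limma). The number of elements at an unadjusted p under 0.05 was 91 and lay between 26 and 110 over these alternatives. It moved by over 1.5 times in 2 cases: to 26 with no replicate block, where the fit is not paired, and to 58 without rat 408. The no-block fit leaves the differences between rats in the error, and its median standard error was 0.12 against 0.08. Leaving out each pair in turn gave counts from 58 to 110. The difference in array level ran from 0.01 to 0.08 over its alternatives, with exact p-values of 0.4375 or more. RG103, R610, R371 and RG406 kept their direction under each of the 17 alternatives, but this was largely fixed in advance. Several alternatives change only the error model or drop other elements, so the estimate stays the same. Elements picked for a shared direction can hardly reverse when a pair is left out. No alternative brought any of these elements past the adjusted threshold, and their smallest adjusted p (limma) was 0.227, for R371 without rat 408. The higher and lower counts were 50 and 41 with quantile normalization, 55 and 12 with values as deposited and 37 and 39 with median scaling. With normexp, chosen after seeing the data, they were 50 and 53 before quantile normalization and 29 and 75 before median scaling; the cause was not tested. The 5 numbered pairs are the same samples as those left without the unnumbered pair. A mean over probes of one gene was not run, since the codes carry no gene names. The fit reported uses no filter, so an unfiltered fit is the same one. The alternatives for the FAK element and the gene lists were not run. The limit set by signal over background could not be measured without background values.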

Other observations

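The tests of rats 408 and 411 by brightness, of R371 by median scaling and of the 0 calls by splits were chosen only after their results were seen. A screen of 19 sets of 6 values for a sample far from the others found 0.

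Large differences between the 2 muscles of a rat were spread unevenly over the rats. In rat 408, 43 elements differed more than 2-fold, 19 higher and 24 lower in the FAK muscle. There were 15 such elements in rat 405, 13 in rat 411, 11 in the unnumbered pair, 5 in rat 410 and 3 in rat 409. The changes of rats 408 and 411 correlated at 0.480 across elements (elements are not independent replicates), while the other 14 combinations of rats lay between -0.08 and 0.26. Of the elements over 2-fold in these rats, 9 were shared. Independent lists would share 0.47 if every element were equally likely to pass 2-fold. Brighter elements varied more, with a median standard error of 0.10 in the brightest 25% against 0.06 in the dimmest 25%. More than 0.47 could therefore be shared without a link between the rats. Of the 9, 8 moved the same way, 6 lower and 2 higher in FAK. All 8 were in the brightest 25% of elements. Their median change, signed by that direction, was 2.12 in rat 408 and 1.42 in rat 411. It was 0.19 in rat 410, 0.09 in rat 409, -0.11 in the unnumbered pair and -0.27 in rat 405. The 8 were picked for changes over 2-fold in rats 408 and 411, so larger values in these rats were fixed in advance. The contrast with the other rats adds no support.

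For these shared changes, noise of dim elements is argued against by a correlation of 0.645 within the brightest 25% of elements, against 0.11 in the dimmest 25%. Quantile normalization is argued against too, since median scaling gave 0.510, with 0.286 as the highest other combination. The pattern may lie in the empty arrays. The deviations of the empty 408 and empty 411 muscles from the other 3 arrays of their sets correlated at 0.583. The next highest of 48 combinations of arrays was 0.306, the lowest was -0.416 (empty 409 with empty 411), and FAK 408 with FAK 411 gave 0.125. Those 3 arrays include the FAK partner, so the deviations share values with the changes and cannot by themselves place the pattern. A candidate explanation is that the empty muscles of rats 408 and 411 differed from the others in something other than the construct. These muscles come from different brightness sets. Whether such a difference would be tissue composition, injury, dissection or RNA handling stays open, because the element codes carry no gene names. A stronger effect of the FAK construct in these rats is not excluded either, because the transfer of FAK was not checked.

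The lower level of R371 in FAK muscles may owe much to the normalization. Quantile normalization gives the few brightest ranks fixed values, and with median scaling the change went from -0.60 to -0.258, within its spread of 0. On the median scale the other 5 of the 6 brightest elements were on average 0.22 higher in FAK, between -0.24 and 0.79 over rats. Set against those on the same array, R371 was lower by a mean change of -0.474 ± 0.24 (SD, n = 6 pairs), in 5 of 6 rats (exact sign-flip permutation test, two-sided, p = 0.0625). Whether R371 was lower or other bright elements were higher on the FAK arrays cannot be told apart with 6 pairs.

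Exchanging the constructs within rats gives 32 splits of the 12 arrays that part all 6 pairs. All 32 called 0 elements at the adjusted threshold, which any split would have matched, so this comparison decides nothing. For the 91 elements at an unadjusted p under 0.05, 2 of 32 splits gave as many, the real one included, and the highest other, with rat 405 exchanged, gave 95, so chance is not excluded. The median over the other splits was 37. For the 61 elements moving one way in all 6 rats, 1 of 32 splits gave as many, the real one; the highest other, again with rat 405 exchanged, gave 60. That is the smallest share 32 splits can give, 3 counts were examined, and the count was 59 with rats 408 and 411 both exchanged and 28 with rat 408 alone, so chance is not taken as excluded for this count either. As a hypothesis, small changes shared by the rats may exist below what single elements can show, but these 6 pairs do not decide it. Without rat 408, which shares its changes with rat 411, the count at an unadjusted p under 0.05 was 58, where evenly spread p-values would give 59.3. Splits were not run on the remaining pairs. With all pairs the other splits had a median of 37, so 59.3 may not be the right reference for 58.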
